A study of Caenorhabditis elegans with 8 samples.

How the data were processed

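The samples were whole-worm RNA of 4 wild-type (N2) and 4 mir-71(n4115) *Caenorhabditis elegans* populations on day 1 of adulthood. Per the labels' protocols, worms were synchronised by bleaching and RNA was taken with Trizol, cleaned on RNeasy columns and made into biotinylated cRNA. The deposited values are 1 table of log2 signals, 29317 probe sets by 8 arrays, on an Affymetrix array. Per the submitters' processing notes the tools were Partek 6.6 and RMA, a method that corrects background, normalises arrays to each other and summarises probes. The order and settings of these steps are not given in the sources used here. That the deposited values are on a log2 scale was read from their range and from the use of RMA. The columns' medians over the tested probe sets were 5.26, 5.25, 5.20 and 5.30 for wild-type replicates 1 to 4 and 5.24, 5.24, 5.25 and 5.25 for mutant replicates 1 to 4. No other per-sample columns were present. Since RMA had already made the arrays alike, no further normalisation was applied, and a change shared by most genes cannot be seen in such values. The median log2 difference over all tested probe sets was 0.02. Scanner files were not used here, so detection above background could not be judged per probe set. Signal level is given for some dim genes and not for all. Below the array medians in the wild type were, among others, F16A11.8 (4.67), irg-1 (4.49), col-12 (4.98) and elo-8 (4.96).

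Probe sets were named through GEO's platform annotation, which can be old. Of the 26192 probe sets it lists, 25546 had 1 gene symbol and 646 several. The other 3125 rows of the value table are unnamed here, are not marked as controls or otherwise, and were left out of the tests. Symbols were updated through the Entrez gene identifier to the RefSeq table of assembly WBcel235, where 25495 probe sets matched and 51 with 1 symbol kept the annotation's name. The array's own genome build is not given in the sources used here, so the assembly was used only for names, chromosomes, gene lengths and which genes neighbour each other. A gene was represented by its brightest probe set over all 8 arrays among those with 1 gene, giving 25478 genes, and a probe set with several genes named none. Of the tested probe sets 146 repeated another's values exactly.

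Groups came from the sample labels. The 4 mutants were compared with the 4 wild types with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group means with no covariate), with Benjamini-Hochberg adjustment over the 26192 probe sets and a threshold of 0.05. Differences are mutant minus wild type on the log2 scale, with their standard errors. The 34 gene lists were fixed before the data were examined. They are reported mir-71 targets and partners, insulin signalling components, genes raised and genes lowered by DAF-16, p38 immune pathway components, intestinal immune effectors, the intracellular pathogen response and vitellogenins. Stress lists cover cytosolic heat shock proteins, endoplasmic reticulum stress, mitochondrial stress, ubiquitin conjugation, proteasome subunits, autophagy and lysosome, and oxidative stress. The metabolic and structural lists are cytochrome P450 enzymes, fat metabolism, cuticle collagens and cytosolic ribosomal proteins. Olfactory neuron signalling, neuropeptide genes, microRNA machinery, heterochronic genes and cell cycle genes complete the pathways. Markers of oocytes and early embryos, zygotic embryos, sperm, moulting, male tissue, intestine, body wall muscle, pharynx, neurons and epidermis stood for tissues that whole worms can hold in unequal shares. Some genes are in more than 1 list. Lists were tested with camera (preset correlation 0.01 and estimated correlation), which compares a list with all other genes, and with fry, which asks whether a list's genes move 1 way on balance, with Benjamini-Hochberg over the 34 lists. Genes per chromosome were tested with Fisher's exact test. The values and calls of genes within 50 kb of mir-71 were planned, and Fisher's exact test of that window was chosen after its values were seen.

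The genes named were taken by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold whose arrays separate by group, and every measured reported target. From each other list it takes up to 2 risen and 2 fallen members with the lowest p, or the member with the lowest p if none passed. It also takes genes within 50 kb of mir-71 that passed, its host gene and the nearest measured gene on each side. Genes named outside the rule are said to be so.

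Alternatives planned before the data were examined were quantile normalisation, subtraction of array medians, the replicate number as a block, leaving out the dimmest 40% of probe sets, eBayes with trend and robust, array weights, an unmoderated linear model, an adjusted p of 0.01, a fold of at least 1.5, each array left out, the median over a gene's probe sets, and windows of 20 and 200 kb. Chosen after seeing the data were all rows of the value table, identical rows counted once, protein-coding probe sets alone, and removal of the trend with gene length (loess, span 0.5, on log10 gene length including introns, per array, over 18847 protein-coding probe sets, 100% of which had a length), also with wild-type replicate 4 left out. The first principal component of the residuals within groups was tried as a covariate as well. A planned test of genes with mir-71 seed matches in their 3' UTRs was not run, since 3' UTR sequences were not used here.

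The steps were tested on simulated arrays drawn from the real means and spreads, 4 against 4, with 200 of 26192 probe sets changed. limma recovered 12.0% of those changed 1.5-fold, 52.0% at 2-fold, 96.0% at 4-fold and 98.0% at 8-fold, with 6 false calls. With 1 of the 34 lists shifted by 0.5, camera called that list and 0 others, with either correlation, over 25478 genes. All simulated values were drawn independently, so genes of a list did not move together. In the data the correlation estimated within the list of reported mir-71 targets was 0.76. The simulation therefore does not show how many false calls correlated genes give, for single genes or for lists.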

Results

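Messenger RNA was measured in synchronised *Caenorhabditis elegans* on day 1 of adulthood, fed on *Escherichia coli* OP50. The samples were 4 of wild type (N2) and 4 of mir-71(n4115), a strain that carries a mutation of the microRNA gene mir-71. Each RNA sample was hybridised to its own 1-colour Affymetrix array. The comparison asked which mRNAs differ when this microRNA, a regulator of lifespan, of olfactory neuron identity and of the immune adaptor gene tir-1, is mutated. The deposited values were log2 signals for 29317 probe sets, of which 26192 had a gene in the platform annotation and were tested. Array medians lay between 5.20 and 5.30. The labels number the samples 1 to 4 in each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples. The precision was limited by the 4 arrays per group and by the distance of wild-type replicate 4 from the other wild-type arrays. Without that array 9401 genes changed, in place of 469. Replicate 4 was nearer to the mutants than to wild-type replicates 1 to 3 for 87.9% of those 9401. Counts without it are therefore not a measure of genotype alone. The median standard error over all arrays was 0.17 for a log2 difference.

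No named probe set measured mir-71 itself, so the mutated gene could not be read in any sample. The noncoding gene F16A11.6, whose annotation overlaps mir-71, stood at 5.14 in the wild type and 5.03 in the mutants, a log2 difference of -0.11 ± 0.10 (SE, n = 4 per group; limma, adjusted p = 0.494). Its values ranged from 5.06 to 5.18 in the wild type and from 4.95 to 5.13 in the mutants. The extent of the n4115 lesion is not given in the sources used here, so this probe set may lie outside it and does not check the labels.

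The 3 wild-type arrays of replicates 1 to 3 resembled each other, with correlations across probe sets of 0.990 to 0.993. The 4 mutant arrays did likewise, at 0.990 to 0.995. Wild-type replicate 4 correlated at 0.986 to 0.993 with the mutants and at 0.961 to 0.976 with the other wild-type arrays. On the first principal component, which held 65.5% of the variance, it stood at 39.9, among the mutants at 22.7 to 49.8. Wild-type replicates 1 to 3 stood at -73.2 to -47.5. The labels place replicate 4 in the wild type and it was kept there throughout.

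**Figure D1:**
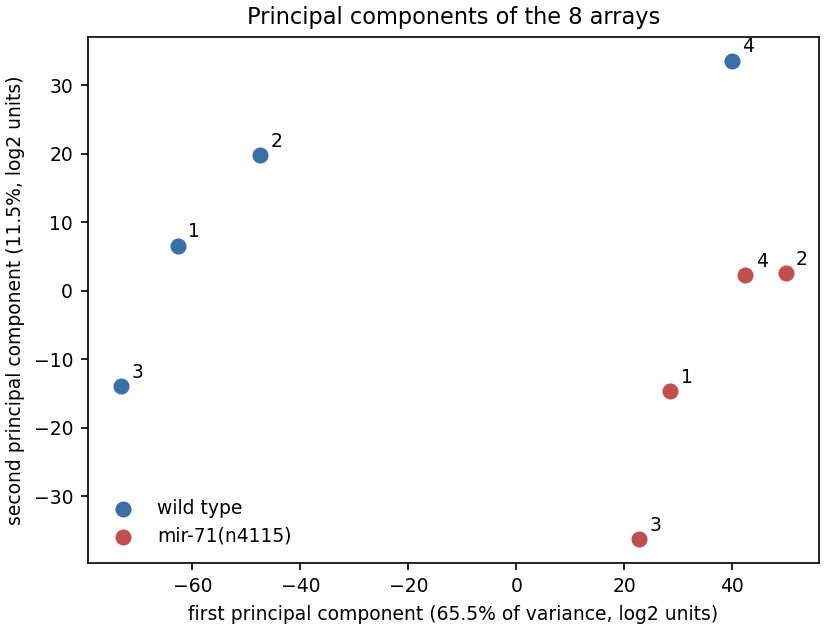
Principal components of the 8 arrays over the 26192 tested probe sets, with the first component (65.5% of the variance) on the x axis and the second on the y axis, in log2 units. Each point is an array with its replicate number. Wild-type replicate 4 lies at 39.9 on the first component, between the mutant arrays, while wild-type replicates 1 to 3 lie at -73.2 to -47.5.

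In mir-71(n4115) worms, noncoding genes next to mir-71 rose most, F16A11.8 by 8.05-fold and F16A11.5 by 6.59-fold. Genes of sperm fell, among them the major sperm protein genes msp-38 and msp-78. The antimicrobial peptide gene cnc-2 fell by 2.96 on the log2 scale and the lysozyme gene lys-7 by 1.78. The small heat shock gene hsp-16.2 rose 4.02-fold, from a dim 2.91 in the wild type that makes its fold uncertain. None of the 13 measured genes reported elsewhere as mir-71 targets or partners passed the test, tir-1 included. Counted over all genes, 469 changed at an adjusted p of 0.05 (limma, Benjamini-Hochberg over 26192 probe sets), of which 312 fell and the others rose. Counted as probe sets, 511 changed, of which 342 fell. Of the 511, 36 were annotated to several genes and name none of the 469. Of the 469 genes, 79 rose and 205 fell by more than 2-fold.

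All 469 changed genes had their 4 mutant arrays on one side of their 4 wild-type arrays. Of all 25478 genes, 2805 were separated in this way, where chance gives 2.86%, but genes are not independent. The changed genes' wild-type replicate 4 value was nearer to wild-type replicates 1 to 3 than to the mutants in 343 of 469. Both this count and the separation of the 469 follow in part from a test in which that array counted as wild type. Without that array 4873 genes rose and 4528 fell, and all 469 remained with the same sign. Without 1 of the other 7 arrays 15 to 48 genes rose and 23 to 130 fell, the fewest without wild-type replicate 2 and the most without wild-type replicate 3.

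Beyond the mir-71 region, the largest rise was that of K11H12.6, from 7.44 ± 0.25 to 9.63 ± 0.11 (mean ± SD, n = 4; adjusted p = 8.11e-04). The other largest rises, from 2.08 down to 1.84 on the log2 scale, were those of F08D12.2, fbxa-192 (an F-box gene), hsp-16.2, H25K10.1, the noncoding gene K12G11.7, cut-4 (a cuticlin), drd-50, F49F1.7 and clec-6 (a C-type lectin). The largest fall was that of C45B2.8, from 8.40 to 5.16, a log2 difference of -3.25 ± 0.47 (SE; adjusted p = 0.0154). It was followed by cnc-2, C15H11.1, Y41G9A.10, Y49G5A.1, T08B2.12, F46C3.6, K12H6.4, C33F10.11, F27E5.7, spch-3 (a sperm chromatin protein) and ins-31 (an insulin-like peptide), with log2 differences from -2.96 to -2.25. Wild-type replicate 4 stood between the other wild-type arrays and the mutants for many of the fallen genes. C45B2.8 read 6.77 there, against 8.79 to 9.07 in wild-type replicates 1 to 3. For ins-31 it read 6.21, within the 5.66 to 6.64 of the other wild-type arrays.

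Of the genes at the mir-71 host gene on chromosome I, ppfr-1 and 3 noncoding genes rose, and F16A11.6 did not pass. The host gene ppfr-1, which encodes a protein phosphatase 4 regulatory subunit, rose from 11.02 ± 0.18 to 11.91 ± 0.05 (SD, n = 4), a 1.84-fold rise (limma, adjusted p = 0.0138). The noncoding gene M04C9.9 rose 2.70-fold (adjusted p = 0.00667), F16A11.5 rose 6.59-fold (adjusted p = 2.15e-05) and F16A11.8 rose 8.05-fold (adjusted p = 2.70e-04). In the WBcel235 annotation all 3 noncoding genes lie within ppfr-1, as do mir-71 and F16A11.6. The genes next to ppfr-1, named after their values were seen, did not pass: dyf-5 differed by 0.04 (adjusted p = 0.871) and rtcb-1 by -0.21 (adjusted p = 0.341). Of 27 measured genes within 50 kb of mir-71, 4 rose and 0 fell, 14.8% against 1.83% of genes elsewhere (Fisher's exact test, 2-sided, p = 0.00142).

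Wild-type replicate 4 stood with the wild type at this locus. F16A11.5 read 6.01 in it and at most 6.24 in wild-type replicates 1 to 3, against 8.75 to 8.87 in the mutants. ppfr-1 read 11.23 in it, 10.80 to 11.09 in the other wild-type arrays and 11.86 to 11.97 in the mutants. With the trend with gene length taken out of each array, the log2 difference of ppfr-1 was 0.37 ± 0.16 (SE) in place of 0.88 ± 0.12, and no longer passed (adjusted p = 0.170). The noncoding genes were outside that correction.

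**Figure D2:**
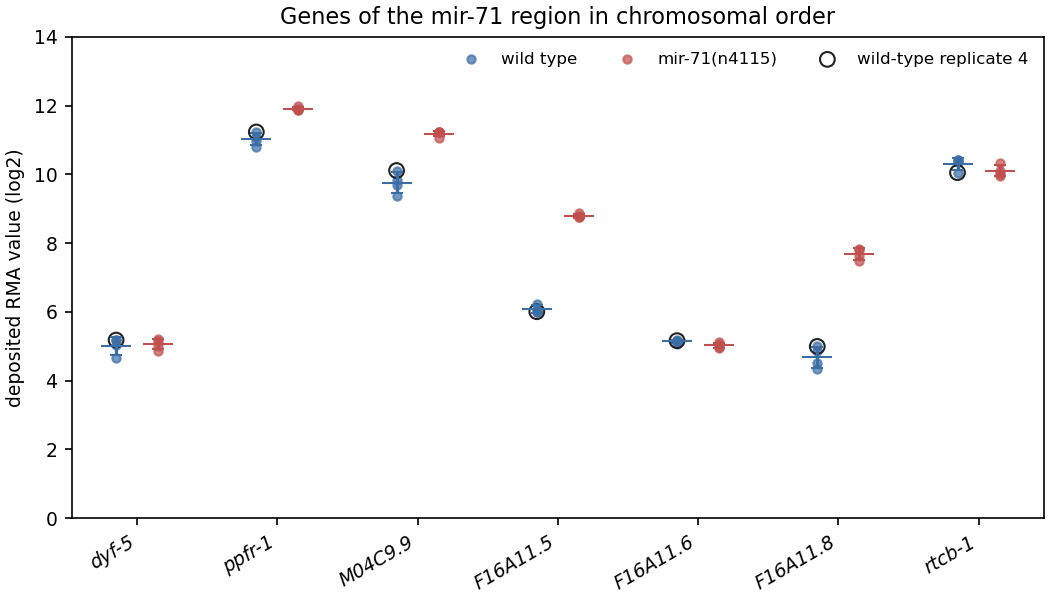
Deposited log2 values (y axis) of genes of the mir-71 region in chromosomal order (x axis), with each array as a point and the mean ± SD of 4 arrays per group as a bar. The 4 mutant arrays lie above all wild-type arrays for ppfr-1, M04C9.9, F16A11.5 and F16A11.8, and wild-type replicate 4 (open circle) lies with the wild type there. F16A11.6, which overlaps mir-71, read 5.14 and 5.03.

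Across chromosomes, changed genes were more frequent on chromosome IV, with 97 of 3905 genes, 78 of them fallen (2.48% against 1.73% elsewhere; Fisher's exact test, 2-sided, adjusted p = 0.00630 over 6 chromosomes). They were less frequent on X, with 65 of 4903 (1.33% against 1.97%; adjusted p = 0.00630), of which 49 rose and 16 fell. Chromosome I, which carries mir-71, held 74 of 3257 (adjusted p = 0.119). II held 68 of 4143 (adjusted p = 0.375), III 46 of 3129 (adjusted p = 0.154) and V 1.96% of 6085 (adjusted p = 0.478). Genes of a family can lie side by side and are not independent.

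Sperm markers fell. Of 23 measured, 7 fell and 0 rose over all probe sets, and 12 fell adjusted over the list alone, with 19 of 23 lower in the mutants. The list's median log2 difference was -0.42. msp-38 went from 7.86 ± 0.21 to 6.52 ± 0.27 (SD, n = 4; limma, adjusted p = 0.0114) and msp-78 from 8.56 ± 0.20 to 7.12 ± 0.37 (adjusted p = 0.0127). The other fallen members, named after their values were seen, were msp-33, spe-11 (a sperm factor needed by the embryo), nspd-1, nspd-2 and ssq-4. Against all other genes the list lay lower (camera, preset correlation, adjusted p = 4.69e-06). With an estimated correlation adjusted p = 0.252. Against no change, which is what fry tests, adjusted p = 0.00670. In wild-type replicate 4 the list lay 0.07 above wild-type replicates 1 to 3 in the median, and the mutants lay below replicate 4, with a median of -0.63. Without that array 10 fell and 1 rose. The median was -0.38 and 4 members fell with the length trend removed. With the length trend removed and replicate 4 left out together, the camera call ended (adjusted p = 0.0903).

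The other germ line and embryo markers did not fall. Of 36 oocyte and early embryo markers 0 were called and 1 had an unadjusted p under 0.05, and 29 were higher in the mutants, with a median of 0.16 (camera adjusted p = 0.0486; estimated correlation, adjusted p = 0.564). That camera call ended with quantile normalisation (adjusted p = 0.0700), without the dimmest probe sets (adjusted p = 0.139) and without wild-type replicate 1 or 3 or mutant replicate 1, 2 or 4 (adjusted p from 0.0830 to 0.101). The lowest p was that of fbf-1, a germline stem cell regulator, at 0.36 ± 0.14 (SE; adjusted p = 0.152). Among 27 zygotic embryo markers cnd-1, a neuronal helix-loop-helix gene, rose by 0.65 (adjusted p = 0.0485) and 0 fell; 7 rose and 1 fell adjusted over the list alone. The median was 0.24 (camera adjusted p = 0.0638, fry adjusted p = 0.0121). Camera called the list with the length trend removed (adjusted p = 0.0250), where cnd-1 no longer passed (adjusted p = 0.0530), with protein-coding probe sets alone (adjusted p = 0.0173), without the dimmest probe sets (adjusted p = 0.0440) and without wild-type replicate 3 (adjusted p = 0.0473). With an estimated correlation these calls were lost (adjusted p from 0.274 to 0.651), and as reported adjusted p = 0.495. Wild-type replicate 4 lay 0.20 above the other wild-type arrays for the oocyte list and 0.18 above them for the zygotic list.

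Moulting markers included noah-1 and noah-2, apical matrix proteins laid down before a moult. noah-2 rose from 7.63 ± 0.51 to 8.77 ± 0.09 (SD, n = 4; adjusted p = 0.0426) and noah-1 from 9.51 ± 0.41 to 10.43 ± 0.06 (adjusted p = 0.0493). Of 27 measured, 2 rose, 0 fell and 25 were not called, while 15 rose adjusted over the list alone. The median was 0.79 (camera adjusted p = 2.01e-05; estimated correlation, adjusted p = 0.495). Wild-type replicate 4 stood 0.88 above wild-type replicates 1 to 3 on this list, and without it 19 members rose. Epidermis markers had 0 of 18 called (11 at an unadjusted p under 0.05) and a median of 0.39 (camera adjusted p = 0.00306; estimated correlation, adjusted p = 0.495). Adjusted over the list alone, 8 rose and 1 fell. Replicate 4 stood 0.75 above the other wild-type arrays there, and nhr-25, a nuclear receptor of epidermis and moulting, read 9.54 in it against 7.99 to 8.36 in them and 9.46 to 9.76 in the mutants. Among cuticle collagens and collagen enzymes, col-135 fell by 0.96 (adjusted p = 0.0124), col-12 fell by 1.52 (adjusted p = 0.0397), 0 rose and the other 115 measured were not called. Adjusted over the list alone, 1 rose and 3 fell. The list's median was 0.06 (camera adjusted p = 0.968), and replicate 4 lay 0.39 above the other wild-type arrays. With the length trend removed the list's median was 0.21 and camera called it (adjusted p = 0.0239), as it did with replicate 4 left out as well (0.36, adjusted p = 3.65e-04). Both calls were lost with an estimated correlation (adjusted p = 0.697 and 0.495). col-12 no longer passed with the trend removed (adjusted p = 0.0519).

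Of the 14 reported mir-71 targets and partners 13 were measured, and 0 rose or fell over all probe sets, with 6 at an unadjusted p under 0.05. Adjusted over the list alone 1 rose, and 12 of 13 were higher in the mutants, with a median of 0.52 (camera adjusted p = 0.00217). With an estimated correlation adjusted p = 0.503. tir-1, which encodes the adaptor of the p38 immune pathway, was 7.64 ± 0.42 in the wild type and 8.26 ± 0.05 in the mutants (SD, n = 4; log2 difference 0.62 ± 0.20 SE, adjusted p = 0.114). Wild-type replicates 1 to 3 read 7.39 to 7.50 for it, wild-type replicate 4 read 8.27, and the mutants 8.20 to 8.31. hbl-1, a heterochronic transcription factor, differed by 1.21 (adjusted p = 0.0798), pdk-1, a kinase of insulin signalling, by 1.23 (adjusted p = 0.164) and alg-1, an Argonaute, by 0.67 (adjusted p = 0.148). lin-42 differed by 0.85, chk-1 by 0.57, unc-43 by 0.52, sek-1 by 0.49, lin-14 by 0.43 and cdc-25.1 by 0.31, with adjusted p from 0.132 to 0.320. age-1 (0.14), vhp-1 (0.07) and unc-31 (-0.01) had adjusted p from 0.428 to 0.958. The list lay 0.82 higher in wild-type replicate 4 than in wild-type replicates 1 to 3, with all 13 members higher. Without replicate 4, 10 rose and 0 fell. With the length trend removed the list's median was 0.34 (camera adjusted p = 0.265) and the difference of tir-1 was 0.07 ± 0.10 (SE). With replicate 4 left out as well the median was 0.47 (camera adjusted p = 0.167). There sek-1, pdk-1, cdc-25.1, chk-1, alg-1, hbl-1 and lin-42 rose, while unc-31 (-0.56, limma adjusted p = 0.00365) and vhp-1 (-0.42, adjusted p = 0.00809) fell.

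Of 19 heterochronic genes 0 were called over all probe sets, 11 had an unadjusted p under 0.05 and 9 rose adjusted over the list alone, with 18 higher and a median of 0.70 (camera adjusted p = 1.08e-05; estimated correlation, adjusted p = 0.495). bed-3 differed by 0.77 ± 0.19 (SE; adjusted p = 0.0736). Of 26 genes of the microRNA machinery 0 were called, 13 had an unadjusted p under 0.05, 23 were higher and the median was 0.40 (camera adjusted p = 3.79e-04; estimated correlation, adjusted p = 0.495). sup-26 differed by 0.74 (adjusted p = 0.0708). Wild-type replicate 4 stood 0.89 above the other wild-type arrays for the heterochronic list and 0.60 above them for the machinery. Their medians with the length trend removed were 0.40 (camera adjusted p = 2.56e-04) and 0.20 (camera adjusted p = 0.0200), both lost with an estimated correlation (adjusted p = 0.480).

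**Figure D3:**
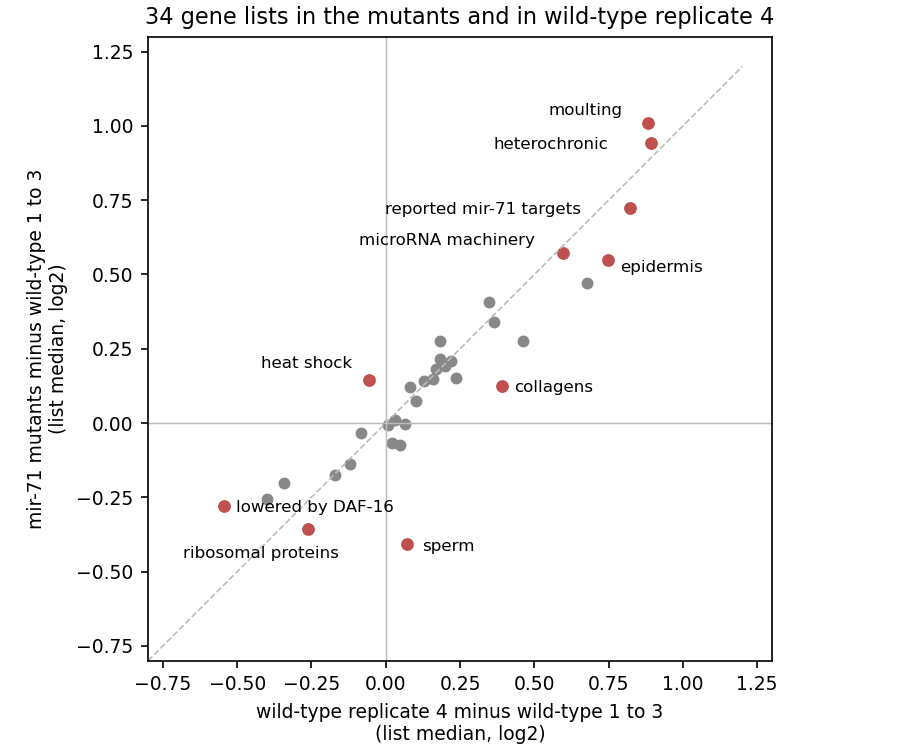
Median log2 difference of the 34 gene lists in wild-type replicate 4 (x axis) and in the 4 mutants (y axis), both from the mean of wild-type replicates 1 to 3. Each point is a list and the dashed line marks equal differences. Most lists lie near that line, with moulting markers at 0.88 and 1.01, while sperm markers lie at 0.07 and -0.41.

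Immune effectors went both ways. Of 57 intestinal immune effectors irg-5 rose by 1.44 ± 0.21 (SE; limma, adjusted p = 0.0151) and clec-85 by 1.11 ± 0.23 (adjusted p = 0.0465). In the same list cnc-2 fell by 2.96, lys-7 by 1.78, cnc-4 by 1.46, irg-1 by 1.01 and thn-2 by 0.82, of which cnc-4 and thn-2 were named after their values were seen. irg-1 no longer passed with the length trend removed (adjusted p = 0.0511). cnc-2 and cnc-4 are antimicrobial peptide genes of the epidermis. Adjusted over the list alone, 5 rose and 17 fell, and the median was -0.19 (camera adjusted p = 0.00320; estimated correlation, adjusted p = 0.495). Wild-type replicate 4 differed from the other wild-type arrays by -0.40 in the median. With the length trend removed the camera call ended (adjusted p = 0.233). For the 18 components of the p38 pathway 0 were called (7 at an unadjusted p under 0.05). Their median was 0.26 (camera adjusted p = 0.0160, and 0.495 with an estimated correlation). From wild-type replicates 1 to 3 the list lay at 0.36 in replicate 4 and 0.34 in the mutants. atf-7, the transcription factor of this pathway, differed by 0.38 (adjusted p = 0.108). The list's camera call ended with the length trend removed (adjusted p = 0.265), without the dimmest probe sets and without mutant replicate 1 (both adjusted p = 0.0504). The 24 genes of the intracellular pathogen response had 0 called (2 at an unadjusted p under 0.05) and a median of 0.00404, with cul-6 at -0.72 (adjusted p = 0.130).

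Among 23 genes raised by the insulin-pathway factor DAF-16, lys-7 fell by 1.78 (adjusted p = 0.0316) and sod-3, a manganese superoxide dismutase, fell from 5.81 ± 0.31 to 4.85 ± 0.27 (SD, n = 4; adjusted p = 0.0423). sod-3 no longer passed with the length trend removed (adjusted p = 0.0517). The other 21 were not called, and 2 fell adjusted over the list alone. The median was 0.00358 (camera adjusted p = 0.466). Of 18 genes lowered by DAF-16 0 were called (5 at an unadjusted p under 0.05), with a median of -0.18, and dod-22 differed by 0.39 (adjusted p = 0.0974). Of 20 insulin signalling components 0 were called (2 at an unadjusted p under 0.05), with a median of 0.11 and camera adjusted p = 0.238. For lys-7 wild-type replicate 4 read 9.13, against 10.22 to 10.78 in the other wild-type arrays and 8.23 to 8.52 in the mutants. Vitellogenins and their regulators had 0 of 9 called (2 unadjusted) and a median of -0.11 (camera adjusted p = 0.738), with pqn-80 at 0.37 (adjusted p = 0.150).

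Of 21 cytosolic heat shock proteins hsp-16.2 rose, from 2.91 ± 0.40 to 4.92 ± 0.28 (SD, n = 4; adjusted p = 0.00667), and 0 fell. These are dim signals, below the array medians. Adjusted over the list alone 3 rose, and the median was 0.20 (camera adjusted p = 0.0486; estimated correlation, adjusted p = 0.495; fry adjusted p = 0.00528). Replicate 4 lay below the other wild-type arrays on this list, with a median of -0.06, and without it the camera call ended (adjusted p = 0.186). It also ended with quantile normalisation (adjusted p = 0.0819), array medians subtracted (adjusted p = 0.0528) and the dimmest probe sets left out (adjusted p = 0.600), and without mutant replicate 1, 2 or 4 (adjusted p from 0.0530 to 0.0850). It held with the length trend removed (adjusted p = 0.00419, 2 members risen), as it did with replicate 4 left out as well (adjusted p = 0.0321). An estimated correlation ended both calls (adjusted p = 0.299 and 0.365). Genes of endoplasmic reticulum stress had 0 of 36 called (9 unadjusted), 27 higher and a median of 0.13 (camera adjusted p = 0.0486; estimated correlation, adjusted p = 0.495; fry adjusted p = 0.0155). atf-6 differed by 0.64 (adjusted p = 0.113). The camera call ended with the length trend removed (adjusted p = 0.0878), with quantile normalisation (adjusted p = 0.0884), without the dimmest probe sets (adjusted p = 0.139), without replicate 4 (adjusted p = 0.0942) and without each other array except wild-type replicate 2 (adjusted p from 0.0569 to 0.0778). The mitochondrial stress response had 0 of 19 called (7 unadjusted) and a median of 0.03, with the protease gene clpp-1 at -0.88 (adjusted p = 0.0911). The SKN-1 oxidative stress list had 0 of 36 called (9 unadjusted) and a median of -0.10 (camera adjusted p = 0.0906), with gst-6 at -1.31 (adjusted p = 0.0851).

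Cytochrome P450 genes fell or were not called. Of 60 measured, cyp-25A1 fell by 1.46 ± 0.18 (SE; adjusted p = 0.01004) and cyp-14A2 by 0.91 ± 0.16 (adjusted p = 0.0279), and cyp-32A1 and cyp-34A9, named after their values were seen, fell by 1.04 and 0.56. Adjusted over the list alone 1 rose and 8 fell. The median was -0.12 (camera adjusted p = 0.00320, and 0.495 with an estimated correlation). From wild-type replicates 1 to 3 it was -0.17 in wild-type replicate 4 and -0.17 in the mutants. The camera call ended with the length trend removed and replicate 4 left out together (adjusted p = 0.0604). In fat metabolism, cpt-4, a carnitine palmitoyltransferase, rose by 0.90 (adjusted p = 0.0173), and the elongase genes elo-7 and elo-8 fell by 1.26 (adjusted p = 0.0230) and 0.83 (adjusted p = 0.0316). Neither elongase gene passed with the length trend removed (adjusted p = 0.0515 and 0.0618). The other 61 of 64 were not called, 2 rose and 2 fell adjusted over the list alone, and the median was -0.02 (camera adjusted p = 0.822).

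Ribosomal protein genes had 0 of 57 called (17 unadjusted) and a median of -0.26, with 47 lower in the mutants (camera adjusted p = 1.01e-04; estimated correlation, adjusted p = 0.495). rpl-23 differed by -0.74 (adjusted p = 0.0865). Wild-type replicate 4 lay at -0.26 from the other wild-type arrays, and with the length trend removed the median was -0.02 and the call ended (adjusted p = 0.705). DNA replication and cell cycle genes had 0 of 47 called (8 unadjusted), with cyd-1, a cyclin, at 0.86 (adjusted p = 0.127). From wild-type replicates 1 to 3 the list lay at 0.17 in replicate 4 and 0.18 in the mutants. From all wild-type arrays its median was 0.13 (camera adjusted p = 0.0486, and 0.495 with an estimated correlation). That camera call ended with quantile normalisation (adjusted p = 0.107), without the dimmest probe sets (adjusted p = 0.139) and without wild-type replicate 1 or 3 or mutant replicate 1, 2 or 4 (adjusted p from 0.0701 to 0.101). Neuron markers had 0 of 30 called (6 unadjusted) and a median of 0.30 (camera adjusted p = 0.00306; estimated correlation, adjusted p = 0.495), with the synaptic gene rab-3 at 0.65 (adjusted p = 0.103). Replicate 4 lay 0.35 above the other wild-type arrays for them, and with the length trend removed the call ended (adjusted p = 0.233).

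The remaining lists had no called member and no camera call as reported. Olfactory neuron signalling had 0 of 42 called (16 unadjusted) and a median of 0.14 (camera adjusted p = 0.0680; 0.0363 without wild-type replicate 4 and 0.0160 with protein-coding probe sets alone), with the G protein gene gpa-13 at 0.56 (adjusted p = 0.0819). Both of those calls were lost with an estimated correlation (adjusted p = 0.260 and 0.426). Neuropeptide genes had 0 of 70 called (16 unadjusted) and a median of -0.00782, with flp-3 at 0.55 (adjusted p = 0.0865). Ubiquitin conjugation had 0 of 37 called (10 unadjusted) and a median of 0.12 (camera adjusted p = 0.0908; 0.0222 with protein-coding probe sets alone, where an estimated correlation gave adjusted p = 0.426), with rpm-1 at 0.44 (adjusted p = 0.0900). Proteasome subunits had 0 of 33 called (4 unadjusted) and a median of -0.00535, with pbs-7 at -0.43 (adjusted p = 0.147). Autophagy and lysosome genes had 0 of 42 called (11 unadjusted) and a median of 0.05, with atg-2 at 0.69 (adjusted p = 0.0774). Male tissue markers had 0 of 20 called (5 unadjusted) and a median of 0.11, with her-1 at -0.55 (adjusted p = 0.125). Intestine markers had 0 of 22 called (10 unadjusted) and a median of -0.04, with the gut esterase gene ges-1 at -1.05 (adjusted p = 0.0534); 3 rose and 3 fell adjusted over the list alone. Body wall muscle markers had 0 of 24 called (3 unadjusted) and a median of 0.30 (camera adjusted p = 0.194; 0.0377 without wild-type replicate 4, where an estimated correlation gave adjusted p = 0.551), with mlc-2 at -0.92 (adjusted p = 0.114). Pharynx markers had 0 of 22 called (7 unadjusted) and a median of 0.20, with abu-1 at -0.94 (adjusted p = 0.0608), and 4 fell adjusted over the list alone. Replicate 4 stood 0.68 above the other wild-type arrays for muscle and 0.46 above them for pharynx.

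In the lists with no called member, the number given as unadjusted is that of members with an unadjusted p under 0.05. An unmoderated linear model called 0 members of all 34 lists, and where no count adjusted over the list alone is given it was 0. In all, camera with the preset correlation called 15 of 34 lists and with an estimated correlation 0 of 34, where the lowest adjusted p was 0.252. fry passed only for sperm markers, zygotic embryo markers, heat shock proteins and endoplasmic reticulum stress. For the other lists that camera called, fry gave adjusted p from 0.0817 (cytochrome P450) to 0.126 (reported mir-71 targets). For 6 lists the median, the mean and the direction of the camera test did not share a sign: genes raised by DAF-16, intracellular pathogen response, vitellogenins, mitochondrial stress, proteasome and pharynx. Over 18847 protein-coding probe sets the difference between mutants and wild type followed gene length, with a rank correlation across genes of 0.40. That of wild-type replicate 4 from wild-type replicates 1 to 3 followed it with 0.40, and that of the mutants from replicate 4 with -0.12. Between 2 arrays of the same group the rank correlation reached a size of 0.265 within wild-type replicates 1 to 3 and 0.230 within the mutants, above the size of the last value. Genes are not independent replicates. In the longest of 5 classes of gene length the mutants lay 0.35 above wild-type replicates 1 to 3 in the median and in the shortest at -0.26. Removing this trend also takes out any real shift that genes of like length share. A list call that ended with the trend removed is therefore not shown to be false.

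**Figure D4:**
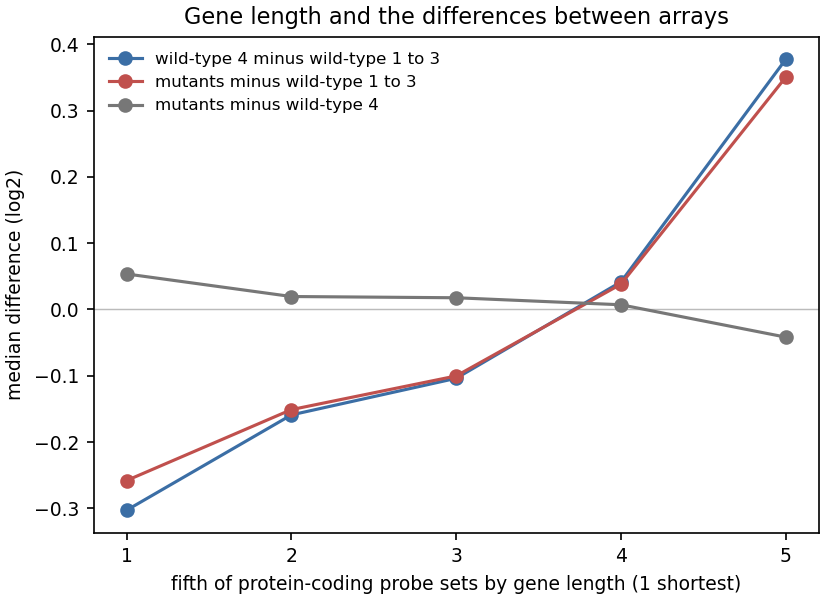
Median log2 difference (y axis) of protein-coding probe sets in 5 equal classes of gene length (x axis, 1 the shortest), for wild-type replicate 4 and the mutants, each from wild-type replicates 1 to 3, and for the mutants from wild-type replicate 4. From the shortest to the longest class the medians go from -0.30 to 0.38 for replicate 4 and from -0.26 to 0.35 for the mutants.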

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

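The tests below of wild-type replicate 4 against a wrong label and of other splits of the arrays were chosen after the result was seen. In each group of 4 arrays, the named genes, list means, first principal component and array medians were searched for a single array far from the other 3. Of 230 such checks 24 stood out, where chance gives about 1 in 20, and 18 of the 24 were wild-type replicate 4. The value given for each is the gap to the nearest array as a share of the group's range, judged against Dixon's critical value for 4 arrays.

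Wild-type replicate 4 was lower than the other wild-type arrays for the fallen genes C45B2.8 (0.879), cnc-2 (0.865), Y41G9A.10 (0.839), T08B2.12 (0.979), F46C3.6 (0.875), C33F10.11 (0.876) and spch-3 (0.836), and for rpl-23 (0.848), her-1 (0.976) and mlc-2 (0.878). It was higher for tir-1 (0.881), alg-1 (0.947), lin-42 (0.846), pqn-80 (0.922) and cyd-1 (0.915). It was also higher in the mean of the collagen list (0.865), the microRNA machinery (0.856) and the body wall muscle markers (0.889). Wild-type replicate 1 was higher than the others for col-12 (0.889) and msp-78 (0.878). Mutant replicate 4 was lower for Y49G5A.1 (0.896). Mutant replicate 3 was lower for M04C9.9 (0.848) and in the means of ubiquitin conjugation (0.854) and fat metabolism (0.911), where the other 3 mutant means had an SD of 0.00305.

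Of the 3125 rows of the value table outside the gene annotation, 33 differed between mutants and wild type when all rows were fitted (limma, adjusted over 29317 rows), 32 higher and 1 lower in the mutants. They are unnamed here.

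Wild-type replicate 4 lay with the mutants on most genes: of 9401 genes that changed when it was left out, it was nearer to the mutants for 87.9%, with a median of 1.05 of the way from wild-type replicates 1 to 3. Mutant RNA under a wild-type label is argued against by the mir-71 host gene, where replicate 4 stood a median of 0.121 of the way to the mutants on the linear scale over ppfr-1, M04C9.9, F16A11.5 and F16A11.8. Its difference followed gene length, but with that trend removed its lowest correlation with the mutants still exceeded its highest with the other wild-type arrays by 0.00892, so the trend alone does not account for it. Worms nearer to a moult and more embryos in the worms both stay open, and these tests do not separate them. With the trend removed the moulting list's median in replicate 4 lay above 100% of 10000 random lists matched on level. That of the zygotic embryo list lay above 97.3%. Genes of a list can move together, which random lists leave out, so these percentiles cannot decide on either cause. Collagens (100%), pharynx (99.99%), epidermis (99.97%), heterochronic genes (99.89%) and oocyte and early embryo markers (99.7%) also lay above the zygotic list. Neuropeptide genes (99.37%) and reported mir-71 targets (99.18%) did too, though neither is a list of moulting or embryo markers. Vitellogenins lay above 0.04%. Without the trend removed their median in replicate 4 was -0.34 from the other wild-type arrays. Their mean was 10.55 in it and 10.55 to 10.64 in those arrays. A difference in stage between wild-type replicates 1 to 3 and the other arrays may be involved. The labels give 1 adult day for all arrays and are silent on this hypothesis.

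Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many changed probe sets as the study's own (511), itself included. That share of 5.71% does not exclude chance at 5%. The other was the split that sets wild-type replicates 1 to 3 and mutant replicate 3 against the rest, with 5244. The remaining splits gave 0. The split with 5244 still sets wild-type replicates 1 to 3 against mutant replicates 1, 2 and 4. It holds much of the real contrast, so the share cannot decide on chance. A split with so many more calls than the real one points to a structure of the samples. It rests on mutant replicate 3 as well as wild-type replicate 4, since wild-type replicates 1 to 3 with any other mutant array gave 0.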

How the results depend on the processing

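Of the results reported, 312 genes fell of 469 changed, 4 genes near the mir-71 locus changed and 15 gene lists were called by camera. The percent of probe sets risen was 0.645 and the percent of probe sets fallen 1.31. These percentages count over the 26192 probe sets of the reported test in every setting, also where fewer or more were fitted. Quantile normalisation, array medians, the dim-probe filter, the fold minimum and the median over probe sets kept each of these counts that they gave within 1.5 times. Quantile normalisation still ended 4 camera calls, the dim-probe filter 5 and array medians 1. All rows of the value table and identical rows counted once, chosen after seeing the data, also kept the counts. Of the named genes' values under all other settings 249 lost the threshold, 123 gained it and 1 changed sign past it, and of the lists' values 48 lost it, 12 gained it and 0 changed sign past it. For the shifts below the cause was not tested, except where the setting's construction gives it.

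With trend and robust eBayes the percent of probe sets risen was 0.405 and genes risen 100. At an adjusted p of 0.01 genes risen were 9 and genes fallen 14 (percent of probe sets risen 0.0344, percent of probe sets fallen 0.0954). The unmoderated linear model gave genes risen 9, genes fallen 9 (0.0344% and 0.0420% of probe sets) and 2 genes near the mir-71 locus. Array weights, at 0.17 for wild-type replicate 4, gave genes risen 5419, genes fallen 5047 (21.5% and 19.8%) and 12 near the locus. Leaving out 1 array gave genes risen from 15 to 4873, genes fallen from 23 to 4528 (0.0611% to 19.3% and 0.134% to 17.8%), 3 to 10 near the locus and 10 to 15 gene lists. The highest gene counts were without wild-type replicate 4, and without another array at most 48 rose and 130 fell. The 200 kb window held 7 changed of 111 genes, and the 20 kb window 4 of 8.

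Chosen after seeing the data, protein-coding probe sets alone, of which 18847 were fitted, gave genes risen 72 (percent of probe sets risen 0.279, of the 26192), since noncoding genes are then not tested. On the same probe sets the length trend removed gave percent of probe sets risen 0.458, again of the 26192 and over 1.5 times as many, with 304 of the 379 reported coding genes remaining. The length trend removed without wild-type replicate 4 gave genes risen 3763, genes fallen 4057 (percent of probe sets risen 14.4, percent of probe sets fallen 15.5, both of the 26192) and 9 gene lists, and there the log2 difference: vhp-1 was -0.42 (adjusted p = 0.00809) and 0.07 as reported. The first residual component as a covariate, in which wild-type replicate 4 weighs most (0.80), gave genes risen 4147, genes fallen 3986 (16.478% and 15.7%) and 9 near the locus. By construction it is built from the residuals of the same fit and leaves the differences as they are while shrinking their error, so its counts are no independent evidence.

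Replicate numbers are shared by the groups, but same-numbered arrays' deviations correlated at 0.19, -0.11, 0.37 and 0.27, and wild-type replicates 1, 2 and 4 correlated best with another number, so the numbers were not taken to pair the samples. With the replicate block 345 genes changed, 257 of the 469 remained, each count stayed within 1.5 times, 2 camera calls ended (heat shock proteins and endoplasmic reticulum stress) and 1 was gained (olfactory signalling). The seed match test was not run, as 3' UTR sequences were not used here. No list was called with an estimated correlation in any setting where lists were tested. Signal over background limits the fold of dim genes such as hsp-16.2 (2.91 in the wild type).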

Other observations

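The tests of RNA classes, of gene families, the host gene's neighbourhood, the noncoding genes' lengths and the sperm list and the ssp family against replicate 4 and the germ line were chosen after the results were seen. Noncoding genes rose more often than protein-coding genes, 79 of 5972 (1.32%) against 77 of 18800 (0.410%; Fisher's exact test, 2-sided, adjusted p = 1.10e-12). They fell less often, 9 (0.151%) against 302 (1.61%; adjusted p = 2.34e-25). Their median signal was 3.60 against 6.57, so many are dim, and genes are not independent.

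Among families of genes sharing a name stem, with at least 10 measured members and each tested for rises and falls (346 tests), the sperm-specific ssp family passed: ssp-33, ssp-34, ssp-35 and ssp-37 fell of 11 measured (Fisher's exact test, 1-sided, adjusted p = 0.00235). All 11 were lower in the mutants, with a median of -0.89, and wild-type replicate 4 differed from the other wild-type arrays by -0.50. With the length trend removed 2 fell. The spe family, with spe-10, spe-11, spe-54 and spe-58 fallen of 32, did not pass (adjusted p = 0.105). Of the 30 probe sets shared by several genes that include major sperm protein genes 19 fell and 0 rose, with a median log2 difference of -1.13. These probe sets cannot be assigned to 1 gene. The mutants lay at -1.02 from wild-type replicate 4 on them, and replicate 4 at -0.14 from the other wild-type arrays.

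Sperm marker genes fell, and 3 explanations were weighed. The length trend alone is argued against, as the list's median stayed at -0.38 with the trend removed, though 4 members fell in place of 7. The axis that sets wild-type replicate 4 apart is argued against for this list, where that array's median shift was -0.180 times that of the mutants, but stays open for the ssp family, where it was 0.508 times, and spch-3 read 4.95 in that array, between the other wild-type arrays and the mutants. A smaller germ line in the mutants predicts a fall of oocyte and early embryo markers, whose median was 0.16 with 29 of 36 higher. No such fall was seen. That list holds embryo markers too, and wild-type replicate 4 lay 0.20 above the other wild-type arrays on it. From replicate 4 the mutants lay at -0.00836 in the median. More embryos in the worms could raise the list, so it cannot decide on the germ line. Fewer sperm at this age may be the source, a hypothesis that these arrays do not test further. The list's camera call ended with the trend removed and replicate 4 left out together (adjusted p = 0.0903).

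Within the mir-71 host gene ppfr-1, ppfr-1 itself and the noncoding genes M04C9.9, F16A11.5 and F16A11.8 rose, while F16A11.6 differed by -0.11 (adjusted p = 0.494). Fisher's exact test of the window gave p = 0.00142, but it was chosen after these values were seen. These overlapping genes can share transcripts and are not independent, so the test cannot decide on chance placement. For ppfr-1 itself the gene length trend stays open: with it removed the difference was 0.37 ± 0.16 (SE) in place of 0.88 ± 0.12, and the call ended because the correction took out over 0.5 of the difference while its SE rose. For M04C9.9, F16A11.5 and F16A11.8 the lowest of the 3 lay above 99.9% of protein-coding genes of its class of gene length (5 classes). These 3 were taken because they had passed, so a high percentile was given in advance and cannot decide on the trend. For these 3 a local effect of the n4115 lesion on transcripts of the host gene may be the source, a hypothesis untested here.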
